A study of Mus with 10 samples.

How the data were processed

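Skin of female BALB/c mice, aged 7-8 weeks, was profiled on 10 Affymetrix mouse gene arrays: 2 control, 4 with a gap of 3 days and 4 with a gap of 7 days after PUVA. Per the labels' protocols, RNA was extracted with a miRNeasy kit and a DNase digest and labelled with the Affymetrix WT PLUS kit. The deposited table holds 1 value per probe set and array, 41345 rows, read here as log2 values made by the authors. The log base and the normalization are not given in the sources used here: the base was inferred from the range, and the array medians of 5.83 to 5.86 show that arrays were made comparable. No scan date or batch was given in the sources used here. The sample titles carry numbers whose meaning is not given, and that of control replicate 2 stands apart from the others. Arrays carry no read depth, and their number limits the precision.

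Probe sets were named from the platform annotation. It listed 25335 with a gene, of which 23521 had 1 symbol and 1814 several, and 16010 rows had no listed gene and are unnamed here. Probe sets with 1 symbol were used, and for the 1082 genes with more than 1 the probe set with the highest mean over all arrays, which gave 22180 genes with no filter on dim signals. Of their Entrez identifiers 21994 were found in the RefSeq table (assembly GRCm38.p6), all with the same symbol. Of 710 symbols written into 28 gene lists, 637 were matched, 7 of them through a synonym. Others, Trp53 and most haemoglobin genes among them, were not analysed here. The blood list had 1 measured member and was not tested: Slc4a1 had log2 changes of -0.36 and -0.12 in the 3-day and 7-day groups against control.

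Group means were fitted over all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 7 residual and 3.514 prior degrees of freedom. The pooled fit was chosen because 2 controls alone give little information on the spread. Benjamini-Hochberg adjustment ran over the genes of each comparison, with a threshold of 0.05. Errors of log2 changes are standard errors of the moderated fit. They take 1 spread per gene over all groups. Where the controls differ more than the PUVA arrays, errors and p-values against control are therefore too small. Lists with at least 5 members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 108 tests (27 lists in 4 comparisons), and also with an estimated correlation and with fry. For fry, passes are counted in its directional test, for a shift in 1 direction. Its mixed test, for changes in either direction, is given only where stated. Camera compares a list with all other genes, and a preset correlation gives too small a p where the genes of a list vary together between arrays: the estimated correlation was 0.672 in the cell cycle list and 0.605 in the hair list. List means per array were compared between the PUVA groups with an exact permutation test over 70 assignments, which counts each direction.

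Design, gene lists, alternatives and the rule for named genes were fixed before the data were examined. For each comparison with control, the rule took the 8 largest rises and falls among genes past the threshold with all treated arrays on the same side of both controls. It took up to 3 members with the smallest p of each list that moved or is named, and a fixed set of genes for damage, senescence and psoriasis. Between the PUVA groups it took up to 5 genes in each direction past the threshold without overlap of the arrays. Gene models, small RNAs and olfactory or vomeronasal receptor genes were counted and not named, unless said otherwise. Values in the text are a selection of the members so named.

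The scripts were tested on simulated data. With 200 of 22180 genes changed, the comparison of 3-day with control skin recovered 82% at a log2 change of 1 and 99.5% at 2. The comparison of the 7-day with the 3-day group recovered 91% and 99.5%. In the former comparison, 6 of 100 unshifted lists had p under 0.05. In these simulations genes varied independently, and each gene had the same spread in all groups. The real controls lay far apart in some lists, so these shares check the scripts and are not the power of the real comparisons. Alternatives were a filter on the lowest 30% of genes by mean, the mean of all probe sets of a gene, all probe sets, quantile normalization, centring on array medians, eBayes with trend and robust settings (for camera, the trend alone), array weights, only the groups compared, other thresholds, lists without shared genes, and leaving out each array. With 1 control left, that control is assumed to vary like the other groups. The replicate numbers follow the order of the samples and pair nothing.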

Results

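RNA from 10 skin samples of female BALB/c mice was measured on Affymetrix gene arrays. The groups were 2 control arrays, 4 arrays of skin with a gap of 3 days after PUVA (the 3-day group) and 4 arrays with a gap of 7 days (the 7-day group). PUVA is psoralen, a light-activated DNA crosslinker, followed by UVA light. Per the labels, 0.25 J/cm2 UVA was given 2 times a week for 2 weeks. The study set PUVA before imiquimod, a drug that gives a psoriasis-like dermatitis in mice, and its title names senescence. The labels do not say whether the arrayed skin had received imiquimod, so none of the comparisons is described as with or without it. The gap is therefore given as labelled and not read as the time from PUVA to sampling. Array medians lay between 5.83 and 5.86 on the log2 scale, and correlations between arrays ran from 0.98762 to 0.99594. The 2 controls correlated at 0.99262, less than control replicate 1 did with each 7-day array, at 0.99443 to 0.99594. The number of arrays, above all the 2 controls, limits the precision. Nothing but the sample titles bears on whether samples came from separate animals, and p-values measure only the spread between these samples, which may be technical.

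The first comparison asks how skin of the 3-day group differed from control skin. Hamp, which encodes the iron-regulating hormone hepcidin, fell from a log2 value of 8.46 ± 0.51 (SD, n = 2) to 3.59 ± 0.33 (SD, n = 4). Genes of the hair shaft and of the inner root sheath, the layer that moulds the growing hair, lay lower in all 34 measured members, with a median log2 change of -0.97. Interferon-stimulated genes lay higher in all 32 members, with a median of 0.65, and matrix genes such as Eln and Lox lay higher in 22 of 24 members. Hamp was the 1 gene of 22180 past an adjusted p of 0.05 in limma, with a log2 change of -4.87 ± 0.44 (SE) and an adjusted p of 0.00826. Its values on the 3-day arrays, 3.41 to 4.09, lay below the lower quartile of every array (4.17 to 4.23). Signal over background was not analysed here, so any log2 difference of Hamp against the 3-day group may be a lower bound. No gene passed in the upward direction. At an unadjusted p under 0.05 there were 2160 genes, against 1109 expected by chance.

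Of the 27 gene lists tested with camera at a preset correlation, 9 passed upward and 11 downward in the 3-day group against control. None of the 20 passed with an estimated correlation, where the lowest adjusted p was 0.256, nor with directional fry, where it was 0.147. In the mixed test of fry, Schwann cells had an adjusted p of 0.0255. In the hair list (adjusted p = 2.46e-27, and adjusted p = 0.256 with an estimated correlation) 26 members were lower when adjusted over the list alone, and 0 over all genes. Krt71 and Krt27, keratins of the inner root sheath, had log2 changes of -4.94 ± 0.75 and -3.86 ± 0.70 (SE), with adjusted p of 0.086 and 0.124. Krtap11-1, a keratin-associated protein of the hair shaft, had -1.09 ± 0.19. The 2 controls were far apart in this list, with means of 5.63 and 7.21, against 5.05 to 5.26 in the 3-day arrays. The SD of the list means was 1.12 in control, 0.098 in the 3-day and 0.047 in the 7-day group. Errors and member counts of hair genes against control pool these spreads, and look more certain than 2 such controls allow. Without control replicate 2 the list's median was -0.26, and without control replicate 1 it was -1.50, both past the threshold at the preset correlation. Krt71 had -3.23, Krt27 -2.08 and Krtap11-1 -0.65 without control replicate 2.

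The cell cycle list, with 40 of 41 members below 0 and a median of -0.36, passed downward (adjusted p = 8.33e-17, and adjusted p = 0.336 with an estimated correlation). No member passed when adjusted over the list alone. Gins1, a DNA replication factor, had a log2 change of -0.59 ± 0.17, Bub1b, a mitotic checkpoint kinase, -0.40 ± 0.11 and the proliferation marker Mki67 -0.44 ± 0.12. DNA repair genes, with 25 of 30 members below 0 and a median of -0.14, passed as well (adjusted p = 3.85e-05, and 0.336 as the adjusted p with an estimated correlation). So did the melanocyte list, with a median of -0.61 (adjusted p = 0.000689, and adjusted p = 0.494 with an estimated correlation), in which Slc45a2, a melanosome transporter, had -0.89 ± 0.22. Without control replicate 2 the adjusted p was 0.293 for the cell cycle, 0.607 for DNA repair (median -0.020) and 0.834 for melanocytes (median 0.044), the last with the direction turned. That control had a cell cycle mean of 7.90, while control replicate 1, at 7.29, lay among the 3-day arrays at 7.23 to 7.31. The cell cycle median was -0.04 without control replicate 2, and Gins1 had -0.21, Bub1b -0.22, Mki67 -0.19 and Slc45a2 -0.43. Without control replicate 1 the medians were -0.67 for the cell cycle and -1.16 for melanocytes. The melanocyte call also ended when the lowest 30% of genes were left out (adjusted p = 0.0511), where the median of the members left was larger, at -0.85.

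The 9 lists that passed upward in the 3-day group were of interferon-stimulated genes, secretory factors, matrix and cell types, while T cells (adjusted p = 0.0986) and the IL-17 list (13 members above 0 and 13 below, adjusted p = 0.674) did not pass. The interferon-stimulated list passed (adjusted p = 2.58e-16, and adjusted p = 0.301 with an estimated correlation). Irf7, a regulator of interferon responses, had a log2 change of 0.95 ± 0.28, Usp18, which limits interferon signalling, 0.78 ± 0.24 and the chemokine Cxcl11 0.78 ± 0.20. The fibroblast and matrix list had a median of 0.45 (adjusted p = 2.77e-10, and adjusted p = 0.256 with an estimated correlation), with 7 members higher when adjusted over the list alone. Without control replicate 1 its median was 0.22, still past the threshold. Lox, which crosslinks collagen and elastin, had 0.98 ± 0.22, the elastin gene Eln 0.78 ± 0.15 and Col5a2 0.73 ± 0.19. Macrophages (median 0.40, adjusted p = 2.69e-05), with C1qa at 0.75 ± 0.25, had an adjusted p of 0.412 with an estimated correlation. Endothelial cells (median 0.18, adjusted p = 2.8e-05), with the receptor Tek at 0.65 ± 0.18, had an adjusted p of 0.256 there. Schwann cells (median 0.26, adjusted p = 5.13e-05), with the myelin genes Mal at 0.71 ± 0.13 and Mbp at 0.37 ± 0.09, had an adjusted p of 0.256. Mast cells (median 0.29, adjusted p = 0.000129), with the protease gene Cpa3 at 0.52 ± 0.14 and Mrgprb1 at 0.70 ± 0.13, had an adjusted p of 0.336. Without 3-day replicate 3, whose mast cell mean was 7.34, their median was 0.18, still past the threshold. Senescence-associated secretory factors (median 0.21, 32 of 41 members above 0, adjusted p = 5.22e-05) had an adjusted p of 0.256 with an estimated correlation. The collagenase gene Mmp13 of this list had 0.89 ± 0.28 (0.55 without control replicate 2). Whether senescent cells made these factors was not tested. Neutrophils (median 0.074, adjusted p = 0.0338) and dendritic cells (median 0.12, adjusted p = 0.0437) had adjusted p of 0.256 and 0.629 with an estimated correlation. The neutrophil call ended without control replicate 2 (adjusted p = 0.427, median 0.037) and without 3-day replicate 2 (0.107, median 0.068), and its median was 0.17 without control replicate 1. The dendritic call ended without 3-day replicate 4 (0.439), where the median fell to 0.048. It also ended without control replicate 1 (0.186, median 0.088), and with medians of 0.11 to 0.12 without control replicate 2 (0.0573), 3-day replicate 3 (0.0968) or 7-day replicate 3 (0.0534). With the lowest 30% of genes left out both calls ended (0.4 for neutrophils, median 0.051, and 0.0731 for dendritic cells, median 0.098), and array weights ended the neutrophil call (0.0519, median 0.058).

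Among the lists that passed downward in the 3-day group were several of lipid synthesis and of the epidermis. The psoriasis-like list of epidermal activation did not pass (19 members above 0 and 17 below, median 0.021, adjusted p = 0.833). The sebocyte and fatty acid list had a median of -0.28 (adjusted p = 6.42e-07, and adjusted p = 0.256 with an estimated correlation). Awat2, a wax ester synthase of sebum, had a log2 change of -1.83 ± 0.35 and was the 1 member lower when adjusted over the list alone. The median was -0.16 without 3-day replicate 1, whose list mean was 9.66, or without control replicate 1, still past the threshold. Circadian clock genes had a median of -0.32 (adjusted p = 0.000852, and adjusted p = 0.256 with an estimated correlation), with 7 of 15 lower when adjusted over the list alone, among them Bhlhe41 at -1.03 ± 0.21, Ciart at -0.64 ± 0.16 and Tef at -0.62 ± 0.15. Ciart had -0.38 and Tef -0.31 without control replicate 2. Of the clock genes 5 lay above 0 and 10 below. Terminal differentiation genes of keratinocytes had a median of -0.15 (adjusted p = 0.000169, and adjusted p = 0.629 with an estimated correlation), with Casp14 at -0.59 ± 0.19. Cholesterol synthesis had a median of -0.15 (adjusted p = 0.000492, and adjusted p = 0.496 with an estimated correlation), with Sc5d at -0.74 ± 0.18 (-0.36 without control replicate 1). Basal keratinocytes (median -0.11, adjusted p = 0.0227), adipocytes (median -0.077, adjusted p = 0.0336) and skeletal muscle (median -0.098, adjusted p = 0.0358) had adjusted p of 0.56, 0.629 and 0.72 with an estimated correlation. Without control replicate 1 the calls ended for terminal differentiation (adjusted p = 0.884, median -0.011), cholesterol synthesis (0.298, -0.072), basal keratinocytes (0.339, -0.059), adipocytes (0.378, -0.044) and muscle (0.932, -0.011, with the direction of the test turned). Without 3-day replicate 2 they ended for basal keratinocytes (0.137, -0.070), adipocytes (0.462, -0.0097) and muscle (0.17, -0.054), without 3-day replicate 4 for adipocytes (0.0825, -0.043) and without 3-day replicate 3 for muscle (0.581, -0.0053). Other processing ended some too: the adipocyte call without the lowest 30% of genes (0.0591, median still -0.077), and the muscle call with quantile normalization (0.0527), array weights (0.0697) or only the groups compared (0.0536), with medians of -0.10, -0.078 and -0.098. Medians that moved by over 1.5 times with the call kept were, without control replicate 2, -0.29 for terminal differentiation, -0.17 for basal keratinocytes, -0.25 for cholesterol synthesis and -0.19 for muscle. Terminal differentiation had -0.097 without 3-day replicate 2, muscle -0.17 without 3-day replicate 1 and adipocytes -0.16 without 3-day replicate 3.

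**Figure D1:**
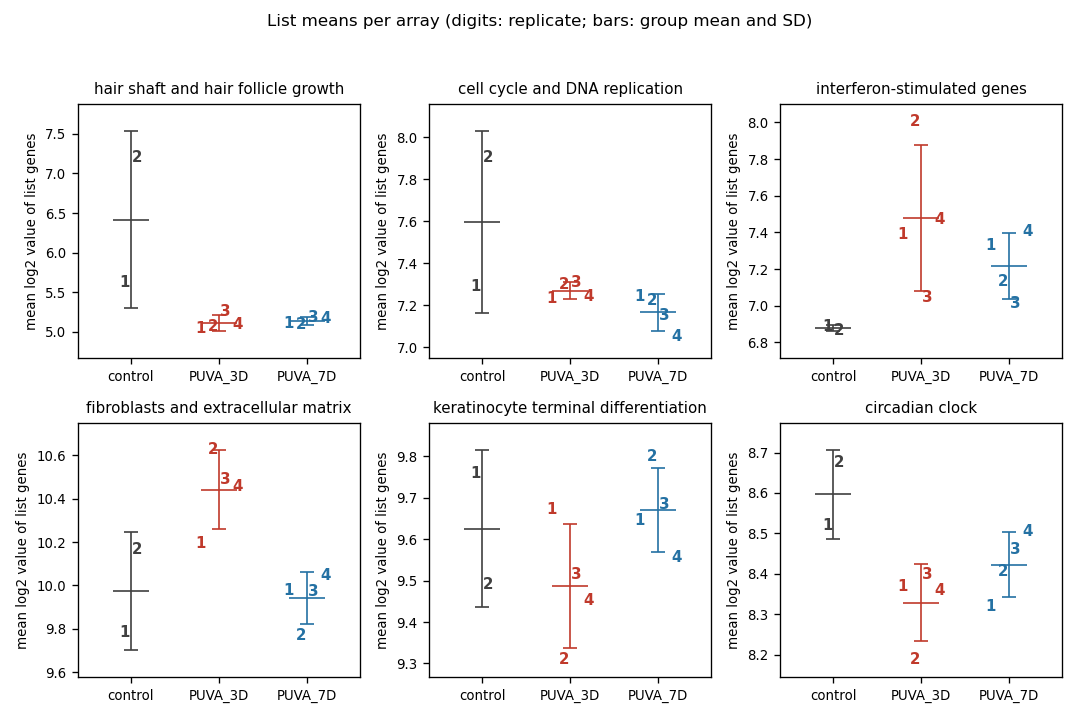
Mean log2 value of the genes of 6 lists on each array (y axis) in the 3 groups (x axis), with digits for replicates and bars for group mean and SD. Control replicate 2 stands at 7.21 in the hair list and at 7.90 in the cell cycle list, and the 4 PUVA_3D arrays, at 10.20 to 10.63, lie above the 4 PUVA_7D arrays, at 9.77 to 10.05, in the matrix list.

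The second comparison asks how skin of the 7-day group differed from control skin. No gene passed in limma, with a smallest adjusted p of 0.392, and 1307 genes had an unadjusted p under 0.05 against 1109 expected by chance. Hair genes lay lower in all 34 members, with a median log2 change of -0.85, and cell cycle genes in all 41, with a median of -0.42. Interferon-stimulated genes lay higher in 28 of 32 members, with a median of 0.30. Hamp stood at 7.18 ± 0.82 (SD, n = 4), a log2 change of -1.27 ± 0.44 (SE) with an adjusted p of 0.777.

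In the 7-day group 3 lists passed upward and 7 downward at the preset correlation, and 0 with an estimated correlation or fry. In the hair list (adjusted p = 3.66e-33, and adjusted p = 0.256 with an estimated correlation) 25 members were lower when adjusted over the list alone. Krt71 had a log2 change of -5.04 ± 0.75, Krt27 -3.79 ± 0.70 and Tchh, the trichohyalin gene of the inner root sheath, -3.66 ± 0.69. These errors and the member count again pool the wide spread of the controls with that of the PUVA arrays, and look too certain. On the 7-day arrays other than replicate 2, Krt27 lay at 4.15 to 4.18, below the lower quartiles of the 7-day arrays (4.21 to 4.23). Its change may therefore be a lower bound. In the cell cycle list (adjusted p = 1.18e-33, and adjusted p = 0.256 with an estimated correlation) 30 members were lower when adjusted over the list alone, among them Bub1 at -0.63 ± 0.14, Gins1 at -0.68 ± 0.17 and the topoisomerase gene Top2a at -0.50 ± 0.12. Without control replicate 2 the cell cycle median was -0.12 and the hair median -0.27, and both calls stayed past the threshold, with Bub1 at -0.38, Gins1 at -0.30, Top2a at -0.24, Krt71 at -3.33, Krt27 at -2.01 and Tchh at -1.98. Without control replicate 1 the medians were -0.78 and -1.45, with -0.24 for DNA repair and -1.17 for melanocytes. DNA repair (median -0.12, adjusted p = 1.36e-07), with the recombination gene Brca2 at -0.55 ± 0.12, and melanocytes (median -0.59, adjusted p = 1.77e-06), with the pigment gene Pmel at -1.25 ± 0.36, had adjusted p of 0.256 and 0.336 with an estimated correlation. Without control replicate 2 both calls ended, with adjusted p of 0.104 and 0.299 and medians of -0.019 and -0.11, and Brca2 had -0.32 and Pmel -0.39.

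The interferon-stimulated list (adjusted p = 6.65e-07, and adjusted p = 0.494 with an estimated correlation) held Usp18 at 0.84 ± 0.24, Irf7 at 0.78 ± 0.28 and Cmpk2 at 0.66 ± 0.21. Endothelial cells (median 0.11, adjusted p = 0.0111), with Tek at 0.65 ± 0.18, and Schwann cells (median 0.11, adjusted p = 0.0437), with Mal at 0.34 ± 0.13, had adjusted p of 0.336 and 0.496 with an estimated correlation. Sebocytes (median -0.13, all 24 members below 0, adjusted p = 0.000148), the clock (median -0.21, adjusted p = 0.00671) and cholesterol synthesis (median -0.054, adjusted p = 0.0437) had adjusted p of 0.336, 0.271 and 0.696 there. Ciart had a log2 change of -0.75 ± 0.16 and Per3 -0.75 ± 0.24, and without control replicate 2 -0.49 and -0.18. The clock genes moved in both directions, with 4 members above 0 and 11 below. At an unadjusted limma p under 0.05, 3 were higher and 5 lower, so the median is not a fall of all clock genes. Single arrays ended several of these calls. Without control replicate 1 the adjusted p was 0.136 for sebocytes (median -0.056), 0.295 for Schwann cells (0.036) and 0.695 for cholesterol synthesis (0.084), the last with the direction turned. Without control replicate 2 it was 0.0722 for the clock (median -0.060) and 0.0758 for endothelial cells (0.083). Without 7-day replicate 3 it was 0.145 for endothelial cells (median 0.079), 0.236 for Schwann cells (0.034) and 0.149 for cholesterol synthesis (-0.052). Without 7-day replicate 4 it was 0.131 for Schwann cells (median 0.044) and 0.406 for cholesterol synthesis (0.0085), and without 3-day replicate 3 it was 0.0591 for Schwann cells (0.11). The cholesterol call also ended without the lowest 30% of genes (0.0821), and the Schwann cell call with only the groups compared (0.0602), with medians as before, -0.054 and 0.11. With the call kept, the sebocyte median was -0.22 and the cholesterol median -0.13 without control replicate 2, and the latter -0.094 and -0.082 without 7-day replicates 1 and 2.

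**Figure D2:**
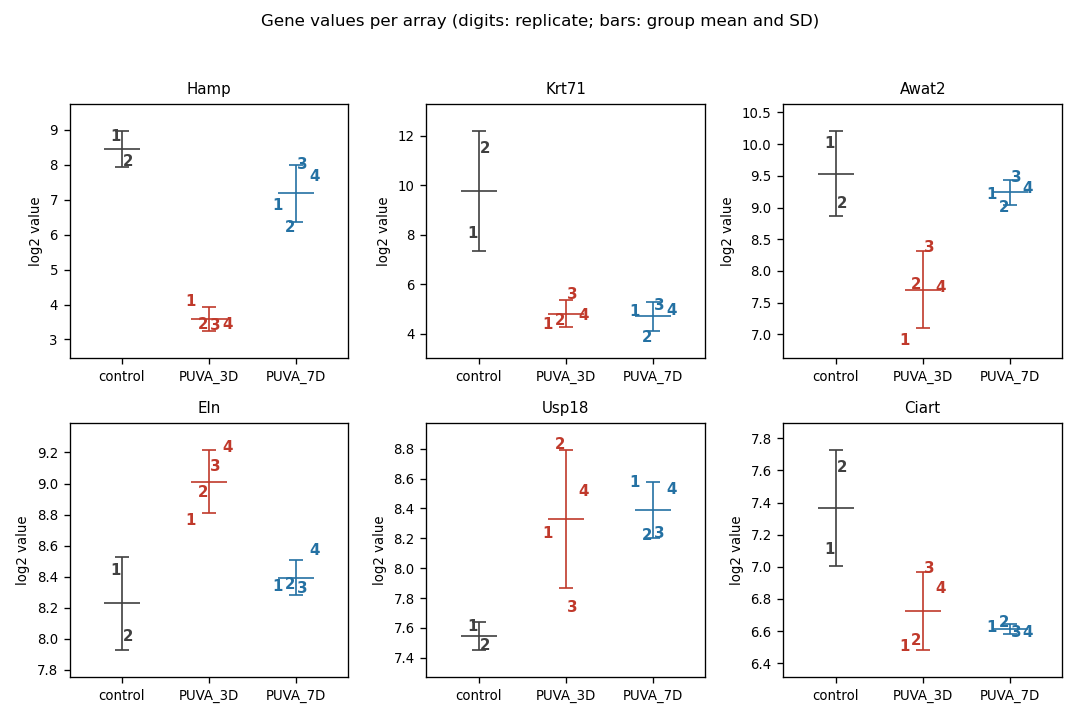
Log2 values of 6 genes on each array (y axis) in the 3 groups (x axis), with digits for replicates and bars for group mean and SD. Hamp lies at 3.41 to 4.09 on the 4 PUVA_3D arrays and at 6.20 to 8.82 on the other 6 arrays, and Krt71 is at 8.04 and 11.5 in the controls.

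The third comparison set the 7-day group against the 3-day group, which asks what differed between the gaps without using the controls as a reference. Hamp was higher at 7 days, with a log2 difference of 3.59 ± 0.36 (SE) and an adjusted p of 0.022, and the 4 arrays of each group did not overlap. Matrix genes were lower at 7 days in 23 of 24 members, with a median of -0.41. Col5a1, a fibrillar collagen gene, had -0.92 ± 0.18, Lox -0.91 ± 0.18 and Eln -0.62 ± 0.12. Genes of keratinocyte terminal differentiation were higher in 35 of 40 members, with a median of 0.20. Besides Hamp, 1 gene passed, the microRNA probe set Mir377 at -1.12 ± 0.12 with an adjusted p of 0.0303, which lies outside the naming rule and is named after its value was seen. Its 7-day values, 2.96 to 3.36, lay below the lower quartile of every array (4.17 to 4.23), so this difference may also be a lower bound. Its call ended with only the groups compared (adjusted p = 0.0559), without either control (0.0559 each), without 3-day replicate 4 (0.0824), and without 7-day replicates 1, 2 and 3 (0.147, 0.186 and 0.129), with log2 differences of -1.07 to -1.12 throughout. At an unadjusted p under 0.05 there were 2166 genes, against 1109 expected by chance. Without 3-day replicate 4 or 7-day replicate 1 no gene passed, with adjusted p for Hamp of 0.0823 and 0.0937, while its log2 difference stayed at 3.54 and 3.71. The count was 1 without either control or without 7-day replicate 2 or 3, and 10, 5 and 6 without 3-day replicates 1, 2 and 3.

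Between the 2 PUVA groups 7 lists passed upward and 9 downward, and 0 with an estimated correlation or directional fry. In the mixed test of fry, the matrix list had an adjusted p of 0.038. In the matrix list (adjusted p = 1.02e-17, and adjusted p = 0.256 with an estimated correlation) 13 members were lower when adjusted over the list alone. The array means of this list separated the groups, which gives the smallest p an exact permutation test of 4 against 4 arrays allows, 0.0286 (two-sided), and an adjusted p of 0.193 over the 27 lists. The same exact p was found for the secretory factors, the IL-17 list and neutrophils. Secretory factors (median -0.14, adjusted p = 0.00417, and adjusted p = 0.256 with an estimated correlation) held Mmp13 at -0.94 ± 0.23 and the protease inhibitor gene Timp1 at -0.67 ± 0.15, and their median was -0.074 without 7-day replicate 2. Mast cells (median -0.26, adjusted p = 0.000392), with Cpa3 at -0.38 ± 0.11, and Schwann cells (median -0.14, adjusted p = 0.00164), with Pmp22 at -0.27 ± 0.07, had adjusted p of 0.336 each with an estimated correlation. The mast cell median was -0.11 without 3-day replicate 3, and the Schwann cell median -0.22 without 7-day replicate 3 or 4. Interferon-stimulated genes (median -0.21, adjusted p = 4.21e-06), with the chemokines Cxcl9 at -1.21 ± 0.34 and Cxcl10 at -0.87 ± 0.21, and macrophages (median -0.25, adjusted p = 0.00137) had adjusted p of 0.496 and 0.5 there. Without 3-day replicate 2, which had the highest interferon mean of all arrays at 8.01, those calls ended, with adjusted p of 0.17 and 0.123 and medians of -0.0092 and -0.16. With its call kept, the interferon median was -0.35 without 3-day replicate 3 and -0.14 without 7-day replicate 3.

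Dendritic cells (median -0.13, adjusted p = 0.00424), the cell cycle (median -0.097, adjusted p = 0.0016) and endothelial cells (median -0.088, adjusted p = 0.0175) were also lower at 7 days, with adjusted p of 0.496, 0.697 and 0.36 with an estimated correlation. The dendritic call ended without 3-day replicate 4 (adjusted p = 0.177, median -0.072), and its median was -0.083 and -0.085 without 7-day replicates 1 and 2. The cell cycle call ended without 7-day replicate 4 (0.0816, -0.056), and the endothelial call without 3-day replicate 3 (0.11, -0.065) or 7-day replicate 4 (0.0677, -0.076). Terminal differentiation (adjusted p = 9.56e-08, and adjusted p = 0.494 with an estimated correlation), with the involucrin gene Ivl at 0.42 ± 0.11, and basal keratinocytes (median 0.13, adjusted p = 0.00151, and adjusted p = 0.451 with an estimated correlation), with Itga3 at 0.26 ± 0.08, were higher. The basal median was 0.080 without 3-day replicate 2. The IL-17 list (median 0.094, adjusted p = 0.0247, and adjusted p = 0.442 with an estimated correlation) held Il22ra1, a subunit of the IL-22 receptor, at 0.37 ± 0.11 and the chemokine Ccl20 at 0.42 ± 0.16 (0.26 without 7-day replicate 3). Its call ended without 3-day replicate 3 (adjusted p = 0.0731, median 0.081) or 7-day replicate 2 (0.11, median 0.032). Skeletal muscle (median 0.11, adjusted p = 0.00562), adipocytes (median 0.052, adjusted p = 0.0358), cholesterol synthesis (median 0.067, adjusted p = 0.0374) and sebocytes (median 0.12, adjusted p = 0.0374) had adjusted p of 0.655, 0.629, 0.682 and 0.615 with an estimated correlation. Awat2 had a log2 difference of 1.54 ± 0.29 and the adipocyte hormone gene Retn 0.58 ± 0.12. Single arrays ended all 4 calls. The adjusted p for muscle was 0.0734 and 0.29 without 3-day replicates 2 and 3, with medians of 0.047 and 0.049. For adipocytes it was 0.59 and 0.102 without 3-day replicates 2 and 4, and 0.287 and 0.0928 without 7-day replicates 2 and 3, with medians of 0.015, 0.037, 0.033 and 0.047. For cholesterol synthesis it was 0.113, 0.253 and 0.0929 without 3-day replicates 1, 2 and 3, and 0.4 and 0.102 without 7-day replicates 1 and 2, with medians of 0.088, 0.058, 0.076, 0.035 and 0.060. For sebocytes it was 0.751 without 3-day replicate 1, where the median fell to 0.0004. It was 0.0683 without 3-day replicate 2, and 0.096 and 0.104 without 7-day replicates 1 and 3, with medians of 0.11, 0.099 and 0.12. With array weights the sebocyte and cholesterol calls ended too, at 0.137 and 0.387, with medians of 0.071 and 0.020. With the call kept, the median was 0.21 for muscle without 3-day replicate 1, 0.12 for adipocytes without 3-day replicate 3 and 0.078 without 7-day replicate 4, and for cholesterol synthesis 0.12 without 3-day replicate 4 and 0.11 without 7-day replicate 4.

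The fourth comparison took the mean of both PUVA groups against control. No gene passed in limma (smallest adjusted p = 0.218), and 1623 genes had an unadjusted p under 0.05. Krt71 had a log2 change of -4.99 ± 0.68, Krt27 -3.82 ± 0.64 and Tchh -3.68 ± 0.63, and without control replicate 2 -3.28, -2.04 and -1.99. The limit on the errors and counts of hair genes, from pooled spreads, holds here too. Of the 27 lists 7 passed upward and 7 downward, and 0 with an estimated correlation. The hair list (adjusted p = 1.4e-34, and adjusted p = 0.256 with an estimated correlation) had 28 members lower when adjusted over the list alone, and the cell cycle list (adjusted p = 1.27e-28, and adjusted p = 0.256 with an estimated correlation) had 23. Their medians were -0.27 and -0.089 without control replicate 2, and -1.48 and -0.74 without control replicate 1, with both calls kept. Interferon-stimulated genes lay higher in all 32 members (adjusted p = 7.6e-14, and adjusted p = 0.336 with an estimated correlation), and every PUVA array, at 7.01 to 8.01, lay above both controls, at 6.87 and 6.89. The matrix list (median 0.16, adjusted p = 0.000893, and adjusted p = 0.496 with an estimated correlation) had its test turn direction without control replicate 1, where the median was 6.875e-05, and a median of 0.38 without control replicate 2. Calls also ended without control replicate 2 for DNA repair (adjusted p = 0.283, median from -0.12 to -0.023) and melanocytes (0.736, from -0.57 to -0.031), and without control replicate 1 for cholesterol synthesis (0.751, from -0.13 to -0.035) and macrophages (0.102, from 0.30 to 0.16). The other passing lists were secretory factors, mast cells, endothelial cells and Schwann cells upward (medians 0.12, 0.18, 0.15 and 0.18) and sebocytes and the clock downward (-0.19 and -0.27). Of these, 3 medians moved by over 1.5 times with the call kept: secretory factors to 0.20 and sebocytes to -0.11 without control replicate 1, and the clock to -0.096 without control replicate 2. So did DNA repair (-0.23) and melanocytes (-1.12) without control replicate 1, and cholesterol synthesis (-0.22) without control replicate 2.

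Counts against control depended on single arrays. Without control replicate 1, which leaves replicate 2 as the only control, 182 genes passed in the 3-day group, 217 in the 7-day group and 226 for the mean of both. Without control replicate 2 these counts were 2, 1 and 1. The 3-day count was 6 without 3-day replicate 2, 4 without 3-day replicate 3, 2 without 3-day replicate 4 and 2 without 7-day replicate 4. Across genes the log2 changes of both PUVA groups against control correlated with r = 0.67, and genes are not independent replicates. Simulated unchanged groups sharing the 2 controls gave r = 0.667, a value set by the numbers of arrays. The covariance was 0.0283 against 0.0176 in the simulation, a difference of 0.0107. The simulation gave each gene the same spread in all groups. Controls that spread more than the PUVA arrays, as in the hair list, would raise the covariance as well. The difference therefore does not show a change shared by both PUVA groups. With a separate single control for each group r was 0.034 or 0.299, and part of any excess may come from the shared controls.

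Genes set out in advance for DNA damage, senescence and psoriasis did not pass in any comparison. Against control in the 3-day group, Cdkn1a, the p53 target that encodes p21, had a log2 change of 0.07 ± 0.13, Cdkn2a, a senescence-associated cell cycle inhibitor, -0.15 ± 0.15, Mdm2 -0.09 ± 0.08 and Lmnb1, a nuclear lamina gene, -0.40 ± 0.17. In the 7-day group they had 0.10 ± 0.13, 0.05 ± 0.15, -0.12 ± 0.08 and -0.33 ± 0.17. Lmnb1 had -0.07 in the 3-day and 0.003 in the 7-day group without control replicate 2. Il17a, Il22, Il23a and Tnf had 0.16 ± 0.15, 0.09 ± 0.10, -0.02 ± 0.11 and 0.02 ± 0.13 in the 3-day group. S100a8 and S100a9, genes of calprotectin, had -0.33 ± 0.12 and 0.13 ± 0.13, Krt16, a keratin of activated epidermis, -0.06 ± 0.27 and Cyp1a1 -0.65 ± 0.33. Cyp1a1 had -0.34 without control replicate 1 or 3-day replicate 1, and S100a8 -0.16 without control replicate 1. S100a8 stood at 4.06 in control, 3.73 in the 3-day and 3.91 in the 7-day group, at the 15.8 percentile of all genes. Trp53 was not analysed here. The p53 target list had adjusted p of 0.934, 0.833 and 0.833 in the 3-day, 7-day and 7-day against 3-day comparisons. The senescence regulator list had 0.444, 0.918 and 0.328, the psoriasis-like list 0.833, 0.444 and 0.343, and the IL-17 list 0.674 and 0.0986 against control. In the psoriasis-like list 3 members were higher in the 7-day than in the 3-day group when adjusted over the list alone. The senescence-associated secretory factors, given above, had camera adjusted p of 5.22e-05, 0.0667 and 0.00417 at the preset correlation. With an estimated correlation they did not pass. T cells had 0.0986, 0.694 and 0.106, NRF2 targets 0.117, 0.286 and 0.482, and aryl hydrocarbon receptor targets 0.684, 0.611 and 0.894. In 5 lists, p53 targets, senescence regulators, IL-17, psoriasis-like and aryl hydrocarbon receptor targets, the mean or median differed in sign from the test in at least 1 comparison, and none of these had passed there.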

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

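Tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the samples, and the gene list tests and exact permutation tests of the lists themselves, which were planned.

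Hair genes lay lower in both PUVA groups, by a mean of -1.29 over the list and the 8 PUVA arrays. A smaller share of epithelium in the PUVA pieces as the whole cause is argued against, since the basal keratinocyte list differed by -0.038. By group it differed by -0.10 at 3 days and 0.028 at 7 days, so a part of the 3-day difference stays open. Its high values, 9.71 to 9.84 as group means, might hide part of a change. Control replicate 1 lay 0.37 above the highest PUVA array, but a single array cannot exclude that the difference rests on control replicate 2. In the cell cycle list the mean of control replicate 1 minus the highest PUVA array was -0.019, which puts it within their range, so that pattern may rest on control replicate 2. The hair growth stage of the control mice stays open beside an effect of PUVA: the controls differed by 1.58 in the hair list, the PUVA arrays by 0.214 over their whole range, and the design has no control of known stage.

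Matrix genes were higher in the 3-day than in the 7-day group. A larger share of dermis as the whole cause is not settled. The matrix list moved by -0.37 more than the endothelial list. It moved by -0.32 more than the mean of the endothelial, mast cell, macrophage and Schwann cell lists. The exact permutation p was 0.0286 for both, the smallest possible. But the matrix list had the largest median shift of the lists that differed between the PUVA groups, which favours such a difference. Against mast cells or macrophages alone, at -0.28 each, p was 0.143. A larger share of dermis as a part of the shift stays open. The mean of those 4 lists moved by -0.18 (exact permutation p = 0.0286), while basal keratinocytes moved by 0.13 (0.114) and terminal differentiation by 0.18 (0.0857), as such a share would give. More fibroblasts in the 3-day pieces stay open. The 8 fibroblast genes other than fibrillar collagens, chosen after the collagens were seen, were all lower at 7 days, with a median difference of -0.26 against -0.41 for the whole list, of which 5 are members. The list mean moved by -0.29 more than their mean (exact permutation p = 0.0286), but their high values, 10.64 on average, might hide part of a change. A change in matrix gene expression with the gap stays open beside it, and these data do not part them.

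Mir377 differed between the PUVA groups, at -1.12 (adjusted p = 0.0303, and 0.0532 to 0.186 in the 8 settings where the call ended), and belongs to the Dlk1-Dio3 cluster, an imprinted region with many small RNAs. Of its 52 measured non-coding RNAs, which can share precursors and are not independent, 51 were lower in the 7-day than in the 3-day group, with a median of -0.43. Mir377 in the 7-day group lay below the lower quartile of every array. So did some members on all arrays, such as Mir376a at 1.89 to 2.31 and Mir376c at 1.89 to 2.55. Signal over background was not analysed here, so such differences may be lower bounds. The long non-coding RNA Rian of this cluster, named after its value was seen, had a log2 difference of -1.58 ± 0.25 (limma adjusted p = 0.128). Mir377 lies outside Rian. Other long non-coding RNAs of the cluster moved less: Meg3 had -0.24 ± 0.098 (limma adjusted p = 0.48) and Dio3os 0.075 ± 0.125 (0.876). For recovery of small RNAs, 515 microRNA and small nucleolar RNA probe sets outside the cluster had a median of 0.067. They were taken without a filter on signal, and probe sets without signal in skin would not move, so such recovery is not excluded. A share of matrix-producing fibroblasts cannot be told apart from a change in the cluster, which moved by -0.080 more than the matrix list (exact permutation p = 0.429).

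Other splits bear on how much the counts mean. Between the PUVA groups 2 genes passed, and 1 of the 35 splits of the 8 arrays, the real one, gave as many (highest other 1). That share is the smallest 35 splits allow, and no gene passed without 3-day replicate 4 or 7-day replicate 1, so chance is not excluded. For lists, adjusted over the 27 of that comparison, the real split gave 16 and the highest other 13, again 1 of 35. The median of the other splits was 7 lists, so at the preset correlation many lists also pass on splits that mix the groups. In the 3-day group against control the real count was 20 and the highest other 17, and in the 7-day group 8 and 14, where 1 and 13 of the 15 splits gave as many, and 15 splits are too few for a share under 0.05. For 2 of 10 arrays against the other 8, taken as 1 group, the real count was 14 and the highest other 17, and 9 of the 45 splits gave as many, so chance is not excluded there.

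The lists that differed between the 7-day and the 3-day group by camera at the preset correlation, none of them with an estimated correlation, had these median log2 differences: secretory factors -0.1444, cell cycle -0.09681, IL-17 0.09378, interferon-stimulated -0.2092, terminal differentiation 0.1974, basal keratinocytes 0.1296, sebocytes 0.115, cholesterol synthesis 0.06658, adipocytes 0.05161, muscle 0.1124, matrix -0.4057, macrophages -0.2513, dendritic cells -0.1324, mast cells -0.2553, endothelial cells -0.08806 and Schwann cells -0.1438. Hamp differed by 3.592. Among 17824 probe sets without exactly 1 symbol, which entered no gene comparison, 2 passed between the PUVA groups.

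Single arrays stood apart from the other 3 of their group in 20 of 296 tests of list means and named genes, and chance flags about 1 in 20. In 3-day replicate 2 this held for Cdkn2a at 5.324 (others 5.88 to 5.89), Itga3 at 8.424, Krt14 at 11.76, Rad18 at 8.031, Tef at 7.044 and Timp1 at 6.306. In 3-day replicate 1 it held for Hamp at 4.087, Mrgprb2 at 7.092 and the NRF2 list at 8.289, and in 3-day replicate 3 for Cldn5 at 6.462. In 7-day replicate 4 it held for Cd86 at 7.066, Eln at 8.566, Itgax at 6.904 and Mrgprb2 at 6.954. In 7-day replicate 2 it held for Fancd2 at 6.038, Krt27 at 4.537 and Mag at 4.694, in 7-day replicate 1 for Cldn5 at 5.835 and Per3 at 7.518, and in 7-day replicate 3 for Trpm1 at 4.442.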

How the results depend on the processing

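All alternatives were planned except leaving out control replicate 2 and 3-day replicate 2 together, chosen after the data were seen. The main counts of genes were 1 (3-day against control), 0 (7-day against control), 2 (7-day against 3-day) and 0 (mean of both against control). With array weights they were 3 in the first and 6 in the third comparison, and at an adjusted p under 0.10 they were 16 and 6. In the third, the filter on the lowest 30% and the fit to only the groups compared gave 1. With both doubted arrays left out they were 5, 1, 4 and 1, without Hamp (adjusted p of 0.0626 in the first and 0.0532 in the third, at -5.18 and 3.54) and without Mir377 (0.0532, at -1.02). Over single arrays left out the ranges were 1 to 182, 0 to 217, 0 to 10 and 0 to 226, each upper end against control without control replicate 1. Of 60 list calls in all (20, 10, 16 and 14), 0 passed with an estimated correlation and 0 with directional fry, in each comparison. The count of lists between the PUVA groups was 10 with both doubted arrays left out. The correlation of fold changes was 0.67, and 0.593 to 0.823 over arrays left out. Quantile normalization, centring on medians, eBayes with trend and robust, and the mean of probe sets moved no count of genes or lists by over 1.5 times. Of the 60 list calls, 60 passed after centring, 60 with trend, 60 with mean probe sets, 60 without shared genes, 59 with quantile normalization, 56 with array weights and 55 without the lowest 30% of genes. The fit to only the groups compared kept 44 and ended 2 of the calls it covers. With both doubted arrays left out 43 passed, 16 ended and 1 turned. Without 1 array the direction of the list test turned for skeletal muscle at 3 days (medians -0.1944 to -0.0053 over arrays left out), melanocytes at 3 days (-1.156 to 0.04413, and 0.08609 with both arrays left out), cholesterol synthesis at 7 days (-0.1277 to 0.08437) and matrix in the mean of both (6.875e-05 to 0.3823). For muscle the median without control replicate 1 was -0.01075. The cause was not tested, except that 1 control left makes that array the reference. The fit to only the groups compared was not run for the mean of both or for the correlation, which use all groups. Signal over background was not analysed here, and low values such as Il22 have an unknown floor.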

Other observations

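The test in this part, and its gene list, were chosen after the values of Fos and Dusp1 were seen. Immediate early genes, transcription factors and regulators switched on within minutes of a stimulus, lay higher after PUVA in 13 of 15 measured members, with a median log2 change of 0.34 for the mean of both groups against control. Fos had 1.52 ± 0.38 (SE, limma adjusted p = 0.486), Dusp1 0.77 ± 0.15 (0.369) and Egr1 0.91 ± 0.34 (0.612), and none passed. The lowest PUVA array mean lay 0.031 above the highest control mean. Fos and Dusp1, which prompted the list, count in these means and among the 13, so this separation is no independent support. A difference in handling or sampling between control and PUVA mice may give higher values of these genes. An effect of PUVA would too, so they cannot be told apart here.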
